A study of Saccharomyces cerevisiae with 91 samples.

How the data were processed

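Micro-C libraries of budding yeast (Saccharomyces cerevisiae) were analysed from the tables that the authors deposited. In Micro-C, cells are crosslinked with formaldehyde, chromatin is cut between nucleosomes with micrococcal nuclease (MNase), nearby nucleosomal ends are ligated to each other, and read pairs from the ligated DNA report which nucleosomes lay close together. Per the labels' protocols, ligation products were gel-purified and enriched on streptavidin beads, amplified by PCR and sequenced as paired ends. The submitters' processing notes name CASAVA 1.8.2, Bowtie2 with no version, and the sacCer3 genome build. How the tables were counted from the alignments is not given in the sources used here.

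Per the file headers, the authors deposited whole-number counts of read pairs at each distance in bp for 4 orientations of the pair (IN-IN, IN-OUT, OUT-IN and OUT-OUT), up to 10000 bp, and whole-number counts of read pairs that span each of 6719 nucleosome-depleted regions (NDRs). Neither is normalised. IN-IN pairs face each other and can come from DNA that was never ligated, so distance profiles were built on the same-direction orientations (IN-OUT and OUT-IN). The deposited gene tables hold a long-fragment and a short-fragment signal per gene and a 2D-normalised score on the log2 scale. Per the file headers each of their columns pools the replicates of a group. The deposited log2 score was read from its values as long over short fragments relative to genes of like length and level, since regression on the log2 long and short signals gave slopes near 1 and -1. It is 0 for genes of 750 bp or less in the table of the 30 to 32 °C groups. The correlation of the score with log2 long over short signal lay between 0.418 and 0.716 across groups. In the table of the 37 °C groups the sheets named long and short hold each other's values. The sheet named long correlated at 0.907 with the long signal and at 0.977 with the short signal of the 30 °C table, and the sheet named short at 0.981 with the long and 0.921 with the short signal, so the sheets were exchanged. The deposited boundary lists give a position and the authors' strength score for each boundary called in wild type, in a joint list and in 4 separate lists. Divided by the value of 1 read in each column, gene-table signals were whole, but no count test was run as each column pools a group.

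Samples were assigned to groups from their labels, and columns to samples by name. In all, 54 sample columns whose names matched no single sample or group were not used. Repeat libraries of one replicate were summed. Over NDRs, their chi-square per degree of freedom ran from 1.08 to 3.26, against 1.17 to 15.9 for pairs of separate replicates. The labels do not state whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The line of totals in the NDR table was not used as library size: in 4 of 45 replicates it lay below the number of pairs listed in the distance tables, and for the library without ligation it gives 29810355 against 58425006 pairs listed.

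Counts of NDR-spanning pairs were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest) in R 4.3.3, in one fit of 49 replicates with the group as the term and Benjamini-Hochberg adjustment over 6719 NDRs at 0.05. All tests were two-sided. The common dispersion was 0.0297. CPM values are counts per 1000000 NDR-spanning pairs after TMM scaling of the library size. DESeq2 1.42.0 was the alternative tool, and its dispersion trend fell back to a local fit. Gene lists were tested on NDRs with fry, which asks whether a list's NDRs move one way on balance, and with camera, which sets them against all other NDRs, both in limma 3.58.1. The preset inter-gene correlation of camera was exchanged for an estimated one as an alternative. An NDR was given to a gene when the start codon lay up to 500 bp downstream or 50 bp upstream, a rule chosen after the tables were seen. By this rule 3590 NDRs had at least 1 gene and 847 had 2. A start codon lay within 500 bp of 53.1% of NDRs against 20.9% of random positions, with a median distance of 172 bp. Gene names and coordinates came from a RefSeq gene table of assembly R64, the assembly that sacCer3 holds, and positions are given in sacCer3. The deposited gene tables list 6644 genes.

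The reach ratio of a library is log2 of same-direction pairs at 500 to 1000 bp over those at 100 to 500 bp. It was compared by exact two-sided permutation of the difference of means, with adjustment over 10 comparisons. The smallest p that 2 against 16 replicates allow is 0.0065, and that of 3 against 16 is 0.001. Nucleosome ladder peaks were read from IN-OUT profiles smoothed over 11 bp. Compaction differences are the score of a group minus that of its control, over 4767 genes at 30 to 32 °C and 4759 at 37 °C, with no test across replicates because each group has 1 pooled column. The median of each list was placed among 10000 random lists of the same size matched on reads in 20 bins, and lists outside the 2.5 to 97.5 percentiles are reported. The log2 of long over short signal was computed with a pseudocount of 0.5 as an alternative. Boundaries of separate lists were called shared within 200 bp and set against 100 shifted lists. Intervals on reads are 95% Poisson intervals. The authors' reads carry no molecular identifiers in the sources used here, so intervals cover counting error only.

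The gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The lists are ribosomal proteins, ribosome biogenesis, stress-induced genes, Yap1 and redox targets, Hsf1 heat shock targets, proteasome, glycolysis, histones, meiosis, sulfur and methionine, galactose, seripauperins, a-specific and alpha-specific mating genes, genes within 20 kb of a chromosome end (subtelomeric) or a centromere (pericentromeric), and the genes deleted or mutated in the study. The centromere was taken as the midpoint between the last left-arm and the first right-arm gene. One listed name matched no gene. For diamide, thiolutin, med1d, the libraries labelled rpd3d, rtt109d, ssu72-2 and the 37 °C groups, the rule takes up to 8 NDRs with the largest rise and 8 with the largest fall among those past the threshold with at least 10 reads per replicate on average and 1 sign in every replicate. For other comparisons it takes up to 3 each way. Of each list with at least 2 members past the threshold it takes up to 4 with the smallest p. For compaction it takes up to 8 genes each way among those with at least the median read number, and up to 4 members of each list outside the percentiles. The deleted gene of a strain is always named. The text prints part of what the rule takes where it gives more than a paragraph can hold, and some items it takes are withheld and not reported here.

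Libraries of several groups share a number in their column names. Residuals of NDR counts correlated at a median of 0.115 between libraries that share it (38 pairs) and at -0.007 between those that do not (567 pairs), so fits with this number as a batch block were added after the data were seen. Also added were fits without wild-type replicate 17, counts without chromosome I, counts without NDRs next to strain marker genes (within 2000 bp of a gene whose reads differ 5-fold from wild type), counts within the range of the W303 library and calls of both treatments against split controls. The other alternatives were DESeq2, the listed pairs of all distances as library size, no filter, every library as a replicate, a fit of 2 groups, the replicate number as a block, leaving out each replicate, other controls, other windows and orientations for the reach ratio, other pseudocounts and read minimums for compaction, and other distances for boundaries. The edgeR procedure was tested on simulated counts over the 6719 NDRs. For diamide it recovered 37.3% of NDRs changed 1.5-fold, 83.6% at 2-fold and 100% at 3-fold, with 4.5% false calls. For med1d the shares were 26.9%, 80.6% and 100% with 5.5% false calls, and for H4d4-14 they were 14.9%, 79.1% and 98.5% with 7.2% false calls. In the real data splits that mix groups called up to 690 NDRs, so these shares may not hold. The list procedure for compaction found shifts of 0.5 in glycolysis and 0.25 in ribosomal proteins in 11 of 11 groups each, and 7 of 154 unshifted lists (4.5%). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.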

Results

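Micro-C read pairs were recorded in a BY4741 wild-type strain of budding yeast grown at 30 °C, in the same strain after 1.5 mM diamide for 30 min (a thiol oxidant) or 3 ug/mL thiolutin for 45 min (a transcription inhibitor), and in strains that carry deletions, histone H4 mutations or temperature-sensitive alleles. A name ending in d marks a deletion. After repeat libraries had been summed, the NDR table held 16 replicates of wild type at 30 °C, 3 each of med1d, rtt109d and ssu72-2 (grown at 32 °C), and 2 each of diamide, thiolutin, H4d4-14 (H4 lacking part of its tail), H4R23A, rnh201d, and libraries labelled rpd3d and top1d. The groups at 37 °C (wild type, rgr1, rsc8-21, scc2-4 and sth1-2), H4K16Q, H4Q93E, H4-WT, W303 and wild type at 32 °C had 1 column each. Per the labels, 37 °C was a timed treatment. The rgr1 allele is rgr1-100 in the sample titles and rgr1-97 in the strain label. Further libraries were made without crosslinking, without ligation or with graded MNase.

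Depth differed widely between libraries. NDR-spanning pairs ran from 105690 to 1304896 in the wild-type replicates at 30 °C. They numbered 386439 and 698916 in diamide, 554434 and 286153 in thiolutin, 84223, 166936 and 448397 in med1d, 404715, 433015 and 854234 in rtt109d, 951070, 392930 and 302253 in ssu72-2, 533761 and 143815 in H4d4-14, 747007 and 877762 in H4R23A, 794934 and 179858 in rnh201d, 478128 and 285556 in the libraries labelled rpd3d, and 165999 and 674637 in those labelled top1d. The wild-type column at 37 °C held 2299974, rgr1 947403, rsc8-21 1201648, scc2-4 1438074 and sth1-2 1164131. The library without ligation held 6551. Wild-type replicate 17, with 146987 pairs, stood apart from the others: its log2 value lay over 1 from the wild-type range at 744 NDRs, and its correlation with the wild-type mean was 0.702 across NDRs, which are not independent replicates.

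The deleted gene was examined first in each strain, as reads within the gene in the pooled gene table, relative to wild type. MED1, a Mediator subunit gene (chromosome XVI, 685898 to 687598), stood at 6.7% of the wild-type level in med1d (95% interval 5.6 to 8.0, 131 reads). RTT109, the gene of the H3K56 acetyltransferase (chromosome XII, 146291 to 147601), stood at 1.0% in rtt109d (0.5 to 1.8, 11 reads). RNH201, which encodes the catalytic subunit of RNase H2 (chromosome XIV, 490317 to 491240), stood at 4.9% in rnh201d (4.0 to 5.8, 120 reads). RPD3, the gene of a histone deacetylase, stood at 89.4% in the libraries labelled rpd3d (83.1 to 95.9, 761 reads), which goes against that label. Reads spanning the RPD3 NDR were 73.3 and 85.4 CPM in the replicates labelled rpd3d, within the wild-type range of 58.5 to 136.5. TOP1, the gene of DNA topoisomerase I, stood at 49.3% in the libraries labelled top1d (47.1 to 51.6, 1844 reads). Its NDR, 262 bp from the start codon, had 21.9 CPM (4 reads) in replicate 1 and 78.0 CPM (61 reads) in replicate 2, against 95.5 ± 19.6 CPM (SD, n = 16) in wild type, so that replicate 2 lay within the wild-type range of 69.5 to 159.2. An NDR outside the deleted part of a gene can keep its reads and then checks nothing.

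**Figure D1:**
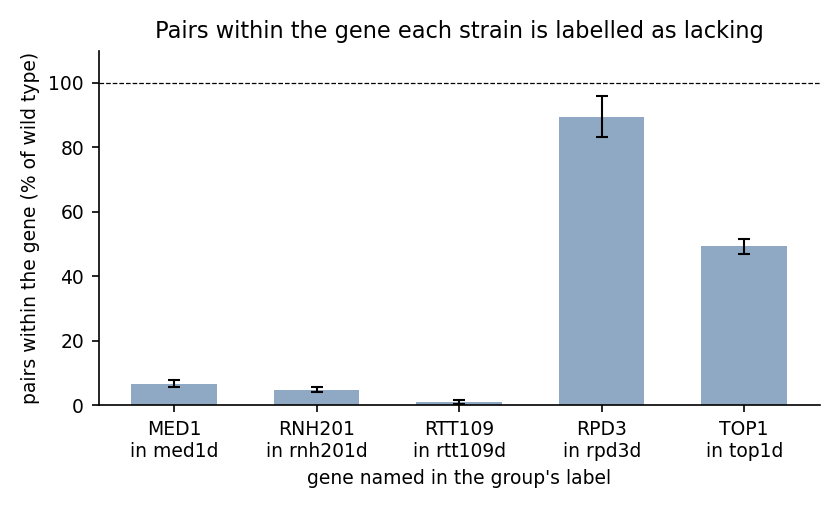
Reads within each deleted gene as a percentage of wild type (bars, vertical position in percent) with 95% Poisson intervals; the dashed line marks 100%. RTT109, RNH201 and MED1 sit at 1.0%, 4.9% and 6.7%, while TOP1 and RPD3 sit at 49.3% and 89.4% in the libraries labelled top1d and rpd3d.

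The same reads gave the genotype around the H4 mutants, whose H3 and H4 genes are carried on a plasmid. The chromosomal HHF1 gene stood at 15.2% of wild type in H4d4-14, 1.2% in H4R23A and 8.1% in H4K16Q, and HHF2 at 15.8%, 4.3% and 9.8%. LYS2 stood at 9.1%, 0.0% and 9.0% and CAN1 at 12.0%, 1.6% and 10.1% in the same order. H4d4-14 and H4K16Q thus kept reads in genes that H4R23A lacks, so wild-type cells or reads mixed into these libraries are not excluded, and all values of H4d4-14 and H4K16Q hold with that limit. For the temperature-sensitive alleles, which are not deletions, the level of the gene checks nothing. The SSU72 gene stood at 154.6% in ssu72-2, and at 155.6% in thiolutin and 149.3% in diamide.

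In wild type, inward-facing IN-IN pairs made up 82.7% ± 5.81 of all listed pairs (SD, n = 16), IN-OUT pairs 4.98% ± 1.62, OUT-IN pairs 4.92% ± 1.56 and OUT-OUT pairs 7.42% ± 2.74. Same-direction pairs were mostly short: 70.0% ± 3.55 lay at up to 500 bp, 12.9% ± 1.75 at 500 to 1000 bp and 17.1% ± 1.98 beyond. IN-OUT pairs formed a nucleosome ladder with peaks at 154.8 ± 7.3, 323.8 ± 4.4, 480.3 ± 13.3 and 646.5 ± 11.3 bp. The distance between the first and second peak was 168.9 ± 6.0 bp, and that from there to the next was 156.6 ± 12.4 bp.

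Both controls had few same-direction pairs. They numbered 63.8 per 1000000 listed pairs without ligation (3725 pairs) and 5957.2 without crosslinking (49283 pairs), against 59506.7 to 162401.6 over the wild-type replicates. The reach ratio, log2 of same-direction pairs at 500 to 1000 bp over those at 100 to 500 bp, was -0.57 without crosslinking and -1.50 without ligation, against a wild-type mean of -2.24. Each control is 1 library, so no test was made. Over all 4 orientations the order turned, with -11.07 without crosslinking and -18.28 without ligation against -5.12 in wild type.

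The reach ratio was lower with more MNase. From 0.25X to 1X MNase the reach ratio moved by -0.49 in the dimer fraction (from -2.10 to -2.59), -0.51 in the monomer, -0.42 in the small and -0.60 in the tri- to tetranucleosome fraction. The share of inward pairs went from 81.0% to 90.4% in the dimer fraction and from 76.3% to 84.8% in the tri- to tetranucleosome fraction. NDR-spanning pairs numbered 1334423 at 0.25X and 536453 at 1X. There was 1 library per fraction and dose, and the direction was the same in all 4 fractions. The 0.5X and 0.75X doses were not analysed here.

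Boundaries between wild-type contact domains lay near gene starts more often than random positions. The joint list held 3061 boundaries with a median spacing of 3514 bp and 1.96 genes per domain. Of these domains 38.8% held 1 gene and 96.3% held 1 to 5. A start codon lay within 300 bp of 61.6% of boundaries, against 27.3% of random positions, an NDR lay within 200 bp of 76.0%, and 11.1% lay inside a gene. The 4 separate lists held 5128 to 5170 boundaries each, at median spacings of 2096 to 2120 bp. In these, 43.7 to 44.8% lay within 300 bp of a start codon, against 27.0 to 27.8% of random positions, 42.8 to 43.1% within 200 bp of an NDR and 47.7 to 48.8% inside a gene. Of the boundaries of one list 50.3% had a partner within 200 bp in another (49.3 to 51.2 over pairs of lists), against 17.2% for shifted lists. Across boundaries, which are not independent replicates, the authors' strength score correlated with log2 NDR-spanning reads at r = 0.743 to 0.777, with lower scores at NDRs spanned by fewer reads.

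Across all comparisons the values are relative to the TMM scaling of NDR-spanning reads. With all listed pairs as library size the median log2 value of all NDRs was 0.159 in diamide, -1.72 in H4d4-14, -0.513 in H4R23A, -0.421 in med1d, 0.191 in rnh201d, 0.247 in the libraries labelled rpd3d, -0.754 in rtt109d, -0.186 in ssu72-2, -0.316 in thiolutin and -0.56 in the libraries labelled top1d. At that scaling no NDR passed the edgeR test in diamide, thiolutin, med1d, rtt109d, H4R23A or rnh201d, 3 passed in ssu72-2 and 5451 in H4d4-14.

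**Figure D2:**
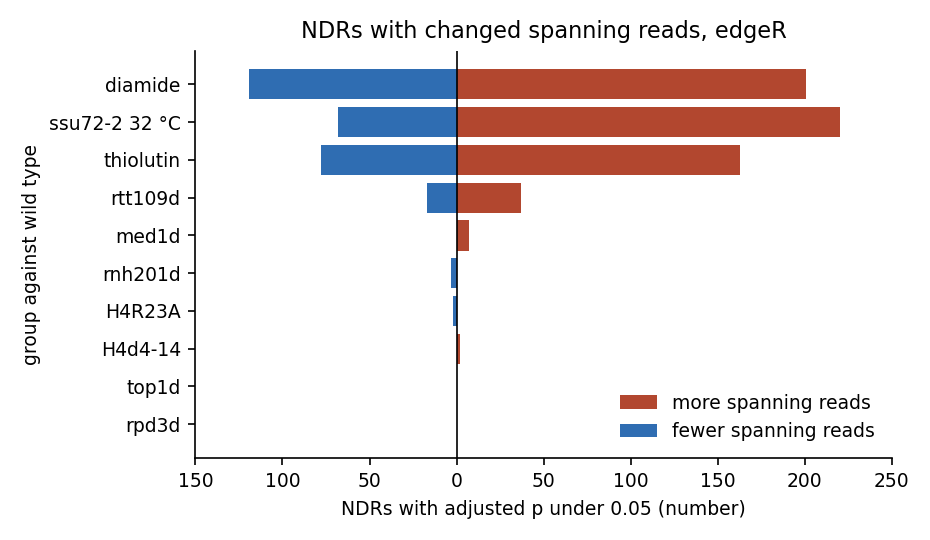
Number of NDRs past an adjusted p of 0.05 in edgeR for each comparison with wild type at 30 °C (horizontal axis, number of NDRs; higher to the right, lower to the left). Diamide (201 higher, 119 lower), thiolutin (163 and 78) and ssu72-2 (220 and 68) have the longest bars, and the libraries labelled rpd3d and top1d have none.

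Diamide oxidises thiols and sets off a redox stress response. NDRs of ribosomal protein genes gained spanning reads after diamide: 30 of 101 rose and none fell over all NDRs tested, 50 rose when adjusted over the list alone, and the median log2 change was 0.50 (fry adjusted p = 3.06e-08, camera adjusted p = 1.32e-23). The largest rises clustered on chromosome X beside RPL39 and RPS22A, where the NDR at position 74856 rose by 1.8 (SE 0.21, edgeR adjusted p = 2.05e-08) from 21.9 ± 5.4 CPM (SD, n = 16) to 80.5 ± 1.5 CPM (SD, n = 2). Inside YEF3, which encodes translation elongation factor 3, the NDR at chromosome XII position 637868 rose by 1.70 (SE 0.18, adjusted p = 1.98e-09) from 53.7 ± 16.8 to 168.3 ± 13.0 CPM. The NDRs of the gene pair RPL39 and RPS22A rose by 1.58 (adjusted p = 3.12e-07), that of RPL13A and RPS16B by 1.36 (adjusted p = 0.000426), and that of RPL12A by 1.01 (adjusted p = 0.000947). Ribosome biogenesis followed at a median of 0.143, with 3 of 60 NDRs called and 3 adjusted over the list alone (fry 0.000694, camera 0.0227, adjusted p = 0.138 with an estimated correlation). Its called members were those of NOG2 (0.80), NOP58 (0.69) and RRP5 (0.69). Outside these lists rises were called at YGK1 (1.51, adjusted p = 7.82e-06), at LEU1, an enzyme of leucine synthesis (1.15, adjusted p = 0.000329), and at PMA1, the plasma membrane proton pump (1.21, adjusted p = 0.001).

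Redox, stress-induced, proteasome and sulfur genes were among the lists that fell after diamide, while Hsf1 targets were not called (0 of 16 NDRs, fry 0.646, camera 0.589). The NDR of GID7, a subunit of the GID ubiquitin ligase, fell by 1.59 (SE 0.26, adjusted p = 1.95e-05) from 181.5 ± 44.0 CPM (SD, n = 16) to 58.3 ± 6.4 CPM (SD, n = 2). That shared by YCL042W and PDI1, which encodes protein disulfide isomerase, fell by 1.32 (adjusted p = 0.000125), that of YDL124W by 1.47 (adjusted p = 0.000426), that of HNT1 by 1.30 (adjusted p = 0.00124), and that of FPR1, a prolyl isomerase gene, by 1.30 (adjusted p = 0.00376). GSH1, the first enzyme of glutathione synthesis, fell by 1.23 (adjusted p = 0.000796) from 81.1 ± 19.9 to 34.6 ± 5.9 CPM. Among Yap1 and redox targets 6 of 18 fell and none rose (1 up and 10 down adjusted over the list alone), with a median of -0.57 (fry 5.06e-06, camera 7.42e-06). They included TRX2, a thioredoxin gene (-0.84, adjusted p = 0.0149), and SOD1, superoxide dismutase, at an NDR shared with ADO1 (-0.87, adjusted p = 0.00918). Stress-induced genes had a median of -0.39 with 2 of 21 called down and 8 adjusted over the list alone (fry 3.06e-08, camera 7.42e-06). Proteasome genes had a median of -0.22 with 1 called up and 5 down of 35, and as many adjusted over the list alone (fry 3.02e-05, camera 0.000774). They included RPN12 (-0.89, adjusted p = 0.0183) and PRE9 (-0.78, adjusted p = 0.0255). Sulfur and methionine genes had a median of -0.34 with 1 of 20 called down and 3 adjusted over the list alone (fry 0.000173, camera 0.000986). These 4 lists and the ribosomal proteins kept their camera calls with an estimated correlation. Subtelomeric NDRs (median -0.21, 4 of 114 called down, 2 adjusted over the list alone) were called by camera (3.18e-05) but not by fry (0.221), with adjusted p = 0.575 with an estimated correlation.

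In all 320 of 6719 NDRs passed in diamide, 201 up and 119 down, of which 173 lay at a gene start. With the batch block 139 passed (87 up and 52 down), of which 123 were also called without it. Without diamide replicate 1 or 2 the count was 87 or 58, and with the batch block the falls of YDL124W (adjusted p = 0.13), HNT1, FPR1, SOD1, TRX2, RPN12 and PRE9 and the rises of RPL13A and RPS16B, LEU1, NOP58 and RRP5 did not pass (0.0528 to 0.377), nor did the ribosome biogenesis list (camera 0.0567).

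Compaction scores after diamide changed the same way as the NDRs in several lists, but not in all. All 120 scored ribosomal protein genes had a higher compaction score than in wild type, that is relatively more long-fragment pairs within the gene, with a median difference of 1.66 against 0.161 to 0.39 for random lists. RPS3 (2.78, 250 long-fragment reads), RPS20 (2.68) and RPL36B (2.62) were among the highest. Ribosome biogenesis genes had a median of 0.65 (51 of 52 higher), led by NOP56 (1.65), CBF5 (1.44), NSR1 (1.41) and NOP58 (1.30), and YEF3 stood at 1.40. Glycolysis had a median of 0.383 (14 of 16 higher), with CDC19, pyruvate kinase, at 0.92, while its NDRs were not called as a list (camera 0.346). Sulfur and methionine genes, whose NDRs fell, stayed within random lists (0.086, 10 of 18 higher). Lower were Yap1 and redox targets (median -0.24, 6 of 20 higher), with GTT2 at -1.06 and TSA1 at -1.02, the proteasome (-0.32, 11 of 33 higher), with PRE2 at -1.02 and PRE1 at -0.79, stress-induced genes (-0.12, 9 of 24 higher), subtelomeric genes (-0.09, 59 of 147 higher), meiosis (-0.04, 12 of 29 higher) and 2 seripauperins (-0.52). SDH9 (-1.14), TVS1 (-0.90) and BNA2 (-0.83) were lowest among well-covered genes. The calls of glycolysis, meiosis and seripauperins were lost under at least 1 other way of scoring, and no test across replicates exists for pooled scores. The reach ratio differed by 0.178 from wild type (exact permutation p = 0.346, adjusted 0.57), by 0.19 and 0.184 within batch.

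**Figure D3:**
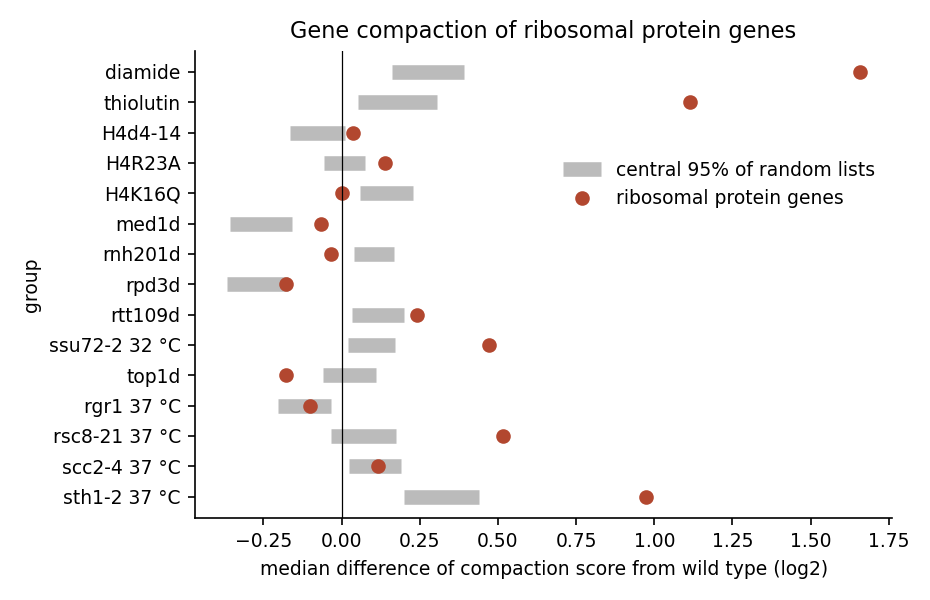
Median compaction difference of ribosomal protein genes (log2 units, points) for each group against its control, with the central 95% of random lists in grey. Diamide (1.66), thiolutin (1.11) and sth1-2 (0.975) lie far above the grey bars, and the libraries labelled top1d (-0.178) lie below.

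After thiolutin, NDRs of ribosomal protein genes rose and those of chaperone genes fell. Of 101 ribosomal protein NDRs 22 rose and none fell over all NDRs tested, 39 rose when adjusted over the list alone, and the median was 0.566 (fry 1.26e-07, camera 1.82e-19). The NDR at chromosome X position 74856 rose by 2.08 (SE 0.22, edgeR adjusted p = 1.77e-09) to 98.9 ± 5.4 CPM (SD, n = 2), that of RPL39 and RPS22A by 1.72 (adjusted p = 6.93e-07), LEU1 by 1.55 (adjusted p = 1.61e-06), an NDR inside ILV5, an enzyme of branched-chain amino acid synthesis, by 1.50 (adjusted p = 0.00019), and that of RPP2A and RPS15 by 1.32 (adjusted p = 0.000295). PMA1 rose by 1.30 (adjusted p = 0.00177) and BRP1 by 1.27 (adjusted p = 0.00453), both next to a gene whose own reads differed 5-fold from wild type. Hsf1 targets fell: 5 of 16 were called down and none up, 7 down when adjusted over the list alone, with a median of -0.487 (fry 8.97e-05, camera 9.64e-06). SSE1, an Hsp110 chaperone gene, fell by 1.59 (SE 0.28, adjusted p = 0.000166) from 68.8 ± 16.4 to 20.2 ± 11.1 CPM. An NDR inside SSA1, an Hsp70 gene, fell by 1.52 (adjusted p = 7.92e-05), one inside HSP104, the disaggregase gene, by 1.43 (adjusted p = 7.31e-06), that of HSP104 itself by 1.25 (adjusted p = 0.000215), that of LST8 and SIS1 by 1.02 (adjusted p = 0.0159) and that of BTN2 by 1.0 (adjusted p = 0.0192). YAR1 (-1.64, adjusted p = 0.00225) and ZPR1 (-1.53, adjusted p = 0.00102) also fell.

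Smaller list shifts followed in thiolutin. Yap1 and redox targets, with 1 of 18 called up and 2 down, did not pass as a list (median -0.179, fry 0.0978, camera 0.228). Of them TRX2 (-1.22, adjusted p = 0.00297) and CCP1, cytochrome c peroxidase (-1.06, adjusted p = 0.0109), fell while GLR1, glutathione reductase, rose by 0.73 (adjusted p = 0.031). Glycolysis had a median of -0.26 with 1 of 20 called and 2 adjusted over the list alone (fry 0.0178, camera 0.0179, adjusted p = 0.227 with an estimated correlation). Histone genes had a median of 0.455 with 0 of 9 called and 2 adjusted over the list alone (fry 0.0161, camera 0.0316, adjusted p = 0.227 with an estimated correlation), and ribosome biogenesis one of 0.181 with 1 of 60 called and 1 adjusted over the list alone (fry 0.00159, camera 0.0258, adjusted p = 0.146 with an estimated correlation). Stress-induced genes (median -0.17, 2 of 21 down, 2 adjusted over the list alone) passed fry (0.00173) but not camera (0.06), and so did a-specific mating genes in thiolutin (median 0.478, 0 of 6 called, 3 up adjusted over the list alone, fry 0.00284, camera 0.114) and diamide (0.275, 1 up, fry 0.00461, camera 0.153). For subtelomeric NDRs the median (0.075) and mean (0.01) lay above 0 and the test pointed down, without a call.

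In thiolutin 241 NDRs passed, 163 up and 78 down, or 67.6% up. With the batch block 48 passed, 45.8% of them up (22 up and 26 down), and 38 of the 48 were also called without it. Of the NDRs named above, the rises of RPP2A and RPS15, PMA1, BRP1 and GLR1 and the falls of LST8 and SIS1, BTN2 and YAR1 did not pass with the block (adjusted p of 0.0786 to 0.642), while the others did. The only wild-type library that shares the number of thiolutin replicate 2 is replicate 17, which stands apart, and without it 23 passed with the block (11 up and 12 down) and 302 without the block. Without replicate 1 the count was 437 and without replicate 2 it was 72.

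Compaction scores in thiolutin were higher at all 120 ribosomal protein genes, with a median of 1.11 against 0.054 to 0.305 for random lists, led by RPL9A (2.33) and RPL37A (2.20). Ribosome biogenesis had a median of 0.413 (44 of 52 higher), with DBP2 at 1.21. Hsf1 targets were lower at all 20 genes, with a median of -0.832 against -0.291 to 0.079, among them MDJ1 (-1.37), HSP78 (-1.15), SSA4 (-1.11) and HSP104 (-0.94), with MBF1 (-1.75) and HSC82 (-1.32) on 3 and 7 reads. Glycolysis (-0.518, 3 of 16 higher), with ENO1 and PGI1 at -0.86 each, stress-induced genes (-0.312, 2 of 24 higher), Yap1 and redox targets (-0.304, 5 of 20 higher), meiosis (-0.225) and 2 seripauperins (-0.705) were also lower, and proteasome genes were higher (0.221, 21 of 33), with RPN11 at 0.83. IRA2, a long gene, had the lowest score of well-covered genes (-1.62), and SWC5 the highest (1.28). The calls of meiosis, proteasome, stress-induced genes and Yap1 targets were lost under at least 1 other way of scoring. The reach ratio differed by -0.22 (exact permutation p = 0.333, adjusted 0.57), by 0.062 and 0.141 within batch, where the second value is set against wild-type replicate 17, the lowest of wild type. Without that library the difference was -0.261 (exact permutation p = 0.154, adjusted 0.309).

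Diamide and thiolutin were compared with the same wild-type libraries, so their changes share chance values. Their log2 changes correlated at r = 0.388 across NDRs, which are not independent replicates, against 0.061 (0.032 to 0.083) for simulated unchanged groups, with a covariance of 0.047 against 0.003. With the wild-type replicates split between the treatments r was 0.266 on average (0.052 to 0.343). The signs were the same at 59.9% of NDRs with shared controls, against 52.3% simulated, and at 55.1% on average with split controls (47.0 to 60.1). Of the calls 77 were up in both, 6 were down in both and 2 were opposite. Independent lists of these sizes would share 4.88 up and 1.38 down. The simulated groups were unchanged, so their mean of 0 called in both cannot serve as a comparison. When each treatment was tested in edgeR against its own part of the wild-type replicates, over 20 splits, a mean of 49.8 were up in both (40 to 56), against 2.98 for independent lists, and 2.9 were down in both (1 to 5), against 0.87. Compared directly, 41 NDRs differed between the treatments, 19 higher and 22 lower in diamide (711 at an unadjusted p under 0.05).

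In med1d, which lacks a subunit of the Mediator coactivator, 7 NDRs rose and none fell (edgeR; 673 at an unadjusted p under 0.05). On chromosome X, the NDR at position 76574 rose by 1.48 (SE 0.25, adjusted p = 0.000816) from 29.2 ± 6.1 CPM (SD, n = 16) to 84.2 ± 3.7 CPM (SD, n = 3), that of RPL39 and RPS22A by 1.42 (adjusted p = 0.00649), that of RPL39 by 1.34 (adjusted p = 0.0115), and one inside SWE1, a cell cycle kinase gene, by 1.12 (adjusted p = 0.0115). NDRs of MET17 (1.35) and inside MET17 (1.36), both with an adjusted p of 0.00649, and at chromosome XII position 735090 (1.14, adjusted p = 0.0419) lay next to genes that the wild-type strain lacks. Wild type had 88 reads in MET17, an enzyme of sulfur assimilation that BY4741 lacks. The med1d libraries also had few reads in BAR1 (0.7% of wild type, 13 reads), so the strain differs from wild type by more than MED1. Ribosomal protein NDRs had a median of 0.182 with 2 called and 3 adjusted over the list alone (fry 0.0299, camera 0.000145, adjusted p = 0.17 with an estimated correlation), and subtelomeric NDRs one of 0.164 (camera 0.0141, adjusted p = 0.712 with an estimated correlation). The batch block gave 464 NDRs (423 up and 41 down), among them the 7, DESeq2 gave 14, and leaving out 1 med1d replicate gave 0 to 6.

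The med1d reach ratio was the lowest of the deletions, -2.69 ± 0.187 (SD, n = 3) against -2.24 ± 0.264 (SD, n = 16) in wild type. The difference of -0.453 did not pass (exact permutation p = 0.0114, adjusted 0.0654). Within batch it was -0.628, -0.842 and -0.26. Without wild-type replicate 17, the lowest of wild type at -2.852, it was -0.494 (permutation, adjusted 0.0245). Compaction scores were lower on the whole (median of all genes -0.286). Against that shift, ribosomal proteins (-0.066, against -0.357 to -0.157), ribosome biogenesis (-0.131), proteasome (-0.067), glycolysis (0.093), Hsf1 targets (-0.029) and Yap1 targets (-0.05) lay high among random lists, with RPL40A at 1.04 and RPL4A at 0.84. Alpha-specific mating genes (-0.865, 0 of 3 higher) and 2 seripauperins (-0.963) lay low. REC8, a meiotic cohesin gene, stood at -1.13, the G1 cyclin gene CLN2 at -1.04 and the ammonium permease gene MEP2 at -1.03. The calls of glycolysis, Hsf1 targets, ribosomal proteins and Yap1 targets were lost under at least 1 other way of scoring.

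**Figure D4:**
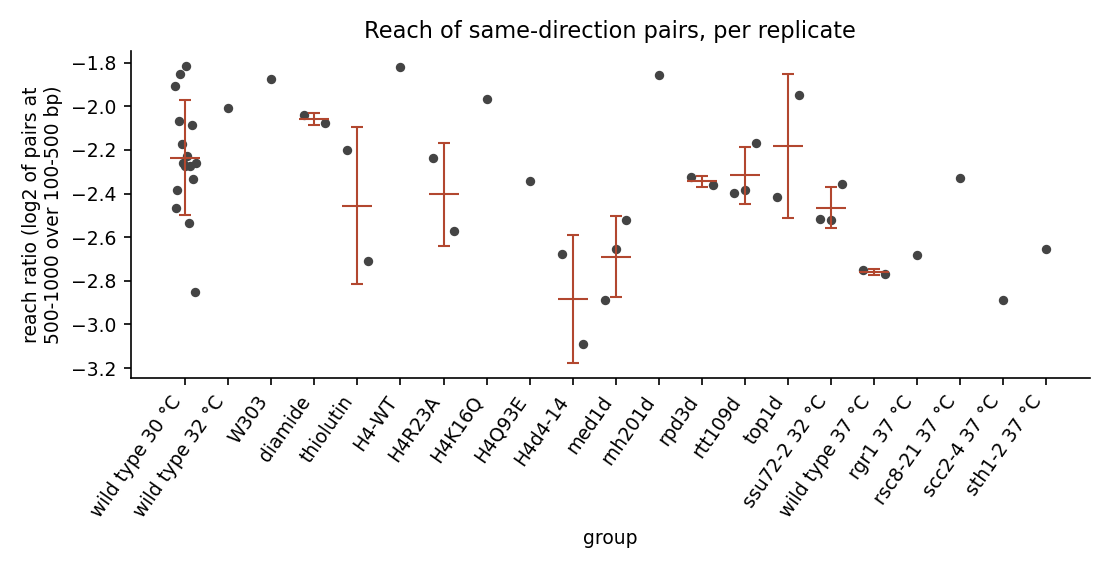
Reach ratio (vertical axis, log2 of same-direction pairs at 500 to 1000 bp over 100 to 500 bp) of each replicate (points) by group, with mean ± SD where a group has at least 2. Wild type at 30 °C has a mean of -2.24 (SD 0.264, n = 16), and H4d4-14 (-2.88), wild type at 37 °C (-2.76) and med1d (-2.69) have the lowest means of the groups with replicates.

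In rtt109d reads of ribosomal DNA rose. Of 54 NDRs that passed, 37 rose and 17 fell (edgeR; 696 at an unadjusted p under 0.05), and the 8 largest rises lay in or beside the rDNA array of chromosome XII. The NDR at position 457821 rose by 2.04 (SE 0.31, adjusted p = 1.96e-05) from 37608.5 ± 11090.9 CPM (SD, n = 16) to 154461 ± 68582.7 CPM (SD, n = 3), that at 460158 by 2.01 (adjusted p = 5.06e-05) and that of TAR1, within the rDNA, by 1.83 (adjusted p = 0.000244). These reads cannot be placed in single copies of the repeat, whose number was not tested. RPS31 (1.06, adjusted p = 0.00124) and RPL22A (0.94, adjusted p = 0.032) also rose. DNM1, beside the deleted RTT109 and so perhaps changed by the deletion cassette, fell by 1.85 (SE 0.27, adjusted p = 9.2e-06) from 82.9 ± 24.8 to 23.8 ± 7.6 CPM. An NDR inside RTT109 itself fell by 1.66 (adjusted p = 1.96e-05), with 15.1, 31.4 and 36.0 CPM in replicates 1, 2 and 3 against 87.1 ± 18.4 in wild type. Near chromosome ends, NDRs inside COS12 (-1.52, adjusted p = 0.00021), at COS12 (-1.21, adjusted p = 0.0196), PAU11 (-1.19, adjusted p = 0.00124) and YMR320W (-0.82, adjusted p = 0.0336) fell, and 9 of the 17 falls lay where the W303 library was over 1 (log2) from wild type. One inside PSE1, an importin gene, fell by 1.14 (adjusted p = 0.00041) from 99.9 ± 15.8 to 45.5 ± 13.4 CPM, and YPS5 by 0.99 (adjusted p = 0.00178).

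Over lists in rtt109d, ribosomal proteins had a median of 0.198 with 2 called and 2 adjusted over the list alone (fry 0.0161, camera 0.000236, adjusted p = 0.17 with an estimated correlation), and pericentromeric NDRs one of -0.131 with 1 called down (fry 0.0659, camera 0.00457, adjusted p = 0.17 with an estimated correlation). The batch block gave 123 NDRs (97 up and 26 down), 43 of them among the 54 (RPL22A and the NDR inside PSE1 did not pass), and leaving out 1 rtt109d replicate gave 11 to 69. Compaction scores were higher at ribosomal protein genes (median 0.241, 89 of 120 higher), with RPL9B at 1.21, and less reduced at ribosome biogenesis genes (0.007, 26 of 52 higher) than in random lists (-0.259 to -0.081). They were lower at pericentromeric (-0.235, 53 of 257 higher) and subtelomeric genes (-0.207), Yap1 targets (-0.317, 5 of 20 higher) and sulfur genes (-0.297, 3 of 18 higher, lost under another way of scoring), and higher at 2 a-specific mating genes (0.211). HIS3, a marker gene, stood at -2.17 and the hexose transporter HXT6 at -1.16, with PRM7 at 0.98. The reach ratio differed by -0.081 (exact permutation p = 0.605, adjusted 0.672), by -0.57 and 0.092 within batch.

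In ssu72-2, an allele of the RNA polymerase II CTD phosphatase gene grown at 32 °C, reads rose along chromosome I. Of 288 NDRs that passed, 220 rose and 68 fell (edgeR; 1123 at an unadjusted p under 0.05), and 93 of them lay among the 100 NDRs of chromosome I. The median log2 change there was 1.10, with 1.22, 0.98 and 0.99 above the other chromosomes in the 3 replicates, and the median change of reads within its 92 genes lay 1.91-fold above that of the other chromosomes. EFB1, a translation elongation factor gene on chromosome I, rose by 1.54 at its NDR, MAK16 by 1.21 (adjusted p = 5.45e-12) and CYS3 by 1.11 (adjusted p = 1.24e-07). Position 31054 of chromosome I rose by 1.67 (SE 0.16, adjusted p = 5.45e-12) from 87.7 ± 27.9 CPM (SD, n = 16) to 253.7 ± 79.4 CPM (SD, n = 3). Away from chromosome I, an NDR inside SAK1, a Snf1-activating kinase gene, at chromosome V position 419673 rose by 1.56 (SE 0.13, adjusted p = 1.52e-13) from 133.5 ± 25.9 to 379.6 ± 70.0 CPM. HSP33 rose by 1.18 (adjusted p = 5.35e-06), RPL21A by 0.91 (adjusted p = 0.0172) and RPL26A by 0.75 (adjusted p = 0.0179).

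**Figure D5:**
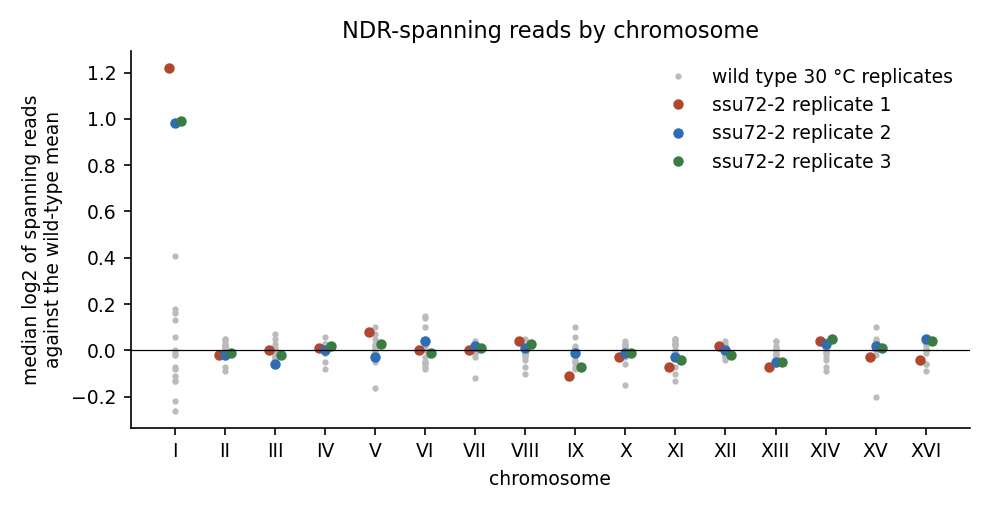
Median log2 change of NDR-spanning reads (vertical axis) on each of chromosomes I to XVI (horizontal axis) for each wild-type replicate (grey) and each ssu72-2 replicate (coloured). On chromosome I the ssu72-2 replicates lie 1.22, 0.98 and 0.99 above their other chromosomes.

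The largest falls in ssu72-2 lay beside hexose transporter genes on chromosome IV: -3.80 at position 1159373 (SE 0.33, adjusted p = 2.22e-13), from 76.0 ± 18.3 to 5.4 ± 0.9 CPM, -3.52 at 1156559 (adjusted p = 3.31e-13), -3.28 at 1157383 (adjusted p = 8.72e-11) and -1.41 at HXT6 (adjusted p = 2.17e-06). The W303 library was also low at position 1159373 (14.5 CPM). Of wild-type reads, ssu72-2 had 0.3 to 0.7% in the ASP3 genes, 0.0% in YBR013C, 0.25% in mitochondrial genes and 7961% in LEU2. A strain difference is thus not excluded for any ssu72-2 call or list. An NDR inside RSC30, of the RSC remodelling complex, fell by 1.20 (adjusted p = 9.79e-06), and one inside the URA3 marker gene by 1.37 (adjusted p = 0.000158), while MET17 rose by 0.88 (adjusted p = 0.00261). Subtelomeric NDRs had a median of 0.243 with 26 called up and 4 down of 114, and 38 up and 6 down adjusted over the list alone (fry 0.0677, camera 1.34e-06, adjusted p = 0.493 with an estimated correlation). Seripauperins had a median of 0.501 with 4 of 15 called up and 7 adjusted over the list alone (fry 0.105, camera 0.000986, adjusted p = 0.571 with an estimated correlation), among them PAU8 (1.05, adjusted p = 1.6e-07) on chromosome I and PAU22 (0.95, adjusted p = 0.00754). Ribosomal proteins had a median of 0.285 with 4 of 101 up and 4 adjusted over the list alone (fry 0.00226, camera 0.000173, adjusted p = 0.174 with an estimated correlation). The histone, sulfur and galactose lists were not called, and the histone (0.073) and sulfur (-0.109) medians differed in sign from their means (-0.083 and 0.043). Without chromosome I 163 NDRs passed (106 up and 57 down), and 3 lists kept their camera calls: ribosomal proteins (0.293, camera 1.15e-07), subtelomeric genes (0.234, 1.15e-07) and seripauperins (0.499, 0.00054). None of them passed with an estimated correlation (0.0552, 0.343 and 0.343). The rises of RPL21A and RPL26A did not pass with the batch block (adjusted p of 0.122 and 0.23). Against the single wild-type library at 32 °C 80 passed, and leaving out 1 ssu72-2 replicate gave 117 to 309.

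Compaction scores in ssu72-2 were higher at 114 of 120 ribosomal protein genes (median 0.473, against 0.021 to 0.172), with RPL34B at 1.19 and RPL37A at 1.11. Ribosome biogenesis genes (-0.004, against -0.221 to -0.067), led by NSR1 (0.77) and NOP1 (0.76), and Hsf1 targets (0.086) also lay high, and meiosis genes (-0.201, lost under another way of scoring) and 2 seripauperins (-0.534) low. PRR2 (-1.10) and BPH1 (-1.0) had the lowest scores. Its reach ratio differed from wild type by -0.228 (exact permutation p = 0.162, adjusted 0.405), by -0.132, -0.25 and -0.094 within batch.

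In H4d4-14 2 NDRs passed (edgeR), and ribosomal protein NDRs rose as a list without a single call. The NDR of RRN11, a gene of RNA polymerase I transcription (chromosome XIII, position 192034), rose by 1.40 (SE 0.25, edgeR adjusted p = 0.00322) from 135.5 ± 32.9 CPM (SD, n = 16) to 371.2 ± 89.3 CPM (SD, n = 2), and the NDR at position 194810 by 1.39 (SE 0.26, adjusted p = 0.00441). Both calls were lost when either H4d4-14 replicate was left out, and with the batch block 498 NDRs passed (471 up and 27 down), including these 2. With all pairs as library size they stood at -0.39 and -0.46. Ribosomal proteins had a median of 0.299 with 0 of 101 called (682 NDRs of 6719 at an unadjusted p under 0.05), by fry 0.000584 and camera 9.41e-10, with adjusted p = 0.00832 with an estimated correlation. Glycolysis had a median of 0.318 with 0 of 20 called (fry 0.0476, camera 0.00899, adjusted p = 0.227 with an estimated correlation and 0.416 with the batch block), and subtelomeric NDRs (0.192, camera 0.000818) and seripauperins (0.307, camera 0.0174) were called by camera alone, each with adjusted p = 0.711 with an estimated correlation.

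The reach ratio of H4d4-14 was the lowest of the groups with replicates, -2.88 ± 0.293 (SD, n = 2), a difference of -0.648 (exact permutation p = 0.0131, adjusted 0.0654), and -0.503 and -0.861 within batch. Without wild-type replicate 17, the lowest of wild type, it was -0.689 (permutation, adjusted 0.0245). Compaction was lower over all genes (median -0.285). Against that shift, ribosomal proteins (0.038, 65 of 120 higher), subtelomeric genes (-0.165) and pericentromeric genes (-0.221) lay high among random lists. The calls of ribosomal proteins and pericentromeric genes were lost under at least 1 other way of scoring. HIS3 stood at -2.47, the Hsp70 gene SSA4 at -1.30 and CLN2 at -1.21.

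In H4R23A AVT2, a vacuolar transporter gene next to the missing CAN1, fell by 1.49 (SE 0.21, edgeR adjusted p = 7.25e-06) from 98.4 ± 18.6 CPM (SD, n = 16) to 33.9 ± 2.9 CPM (SD, n = 2), and CIC1, a ribosome assembly gene, fell by 0.93 (SE 0.19, adjusted p = 0.0321) from 84.7 ± 13.6 to 44.5 ± 0.6 CPM. These were the only calls (453 at an unadjusted p under 0.05), and with the batch block neither passed (0.0732 and 0.0744). Ribosomal proteins had a median of 0.131 (fry 0.127, camera 0.000986, adjusted p = 0.227 with an estimated correlation), glycolysis one of 0.133 (camera 0.0377, adjusted p = 0.362 with an estimated correlation, and with the batch block 0.999 in the other direction) and a-specific mating genes one of 0.31 (fry 0.0119, camera 0.0287, adjusted p = 0.135 with an estimated correlation). Compaction scores were higher at ribosomal proteins (0.139, 73 of 120 higher) and Hsf1 targets (0.118, 13 of 20), and lower at meiosis (-0.171) and subtelomeric genes (-0.119), with DED1, a translation initiation helicase gene, at 0.59 and BNA2 at -0.88. The reach ratio differed by -0.168 (exact permutation p = 0.399, adjusted 0.57), by -0.064 and -0.236 within batch. Against H4-WT, the library of the matching plasmid strain, no NDR passed in edgeR for H4R23A (291 at an unadjusted p under 0.05) or H4d4-14 (741).

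In rnh201d all 3 calls were falls beside genes missing from the strain: RNH201 by 1.78 (SE 0.23, edgeR adjusted p = 1.7e-06) from 113.0 ± 16.9 CPM (SD, n = 16) to 32.8 ± 0.7 CPM (SD, n = 2), LAT1 next to it by 1.60 (adjusted p = 8.6e-05) and AVT2 by 1.24 (adjusted p = 0.00207). No call of this fit was left without NDRs next to such genes (161 at an unadjusted p under 0.05 in all). DESeq2 called 5, the batch block 9, all down, and without replicate 1 none passed in edgeR (275 at an unadjusted p under 0.05). Subtelomeric NDRs (-0.138, camera 0.011) and seripauperins (-0.34, camera 0.0472) were called by camera, each with adjusted p = 0.711 with an estimated correlation. Compaction scores were lower at ribosomal proteins (-0.033, against 0.041 to 0.167), ribosome biogenesis (-0.121, 17 of 52 higher) and glycolysis genes (-0.103, lost under another way of scoring), with MSB4 at 0.58 and ALG3 at -0.57. The distance profile had 1 replicate, at 0.378 above wild type.

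In the libraries labelled rpd3d, whose RPD3 reads go against that label, no NDR passed in edgeR (325 at an unadjusted p under 0.05) or in DESeq2 (259). RPD3's own NDR was at -0.20 (adjusted p = 0.91). Ribosomal proteins had a median of 0.128 (fry 0.174, camera 0.00185, adjusted p = 0.227 with an estimated correlation), glycolysis one of 0.294 (camera 0.0174, adjusted p = 0.241 with an estimated correlation) and subtelomeric NDRs one of 0.119 (camera 0.00867, adjusted p = 0.711 with an estimated correlation). Compaction was low at alpha-specific mating genes (-0.605, 1 of 3 higher) and high among random lists at ribosome biogenesis (-0.057), subtelomeric (-0.064) and Yap1 genes (-0.011), with the first and last lost under at least 1 other way of scoring. LPX1 stood at 0.60 and YTP1 at -0.93. Their reach ratio differed from wild type by -0.108 (exact permutation p = 0.556, adjusted 0.672).

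The libraries labelled top1d kept 49.3% of TOP1, 40.0% of LYS2, 40.4% of CAN1 and 54.3% of BAR1 reads, so mixed strains are not excluded. No NDR passed in edgeR (142 at an unadjusted p under 0.05) or in DESeq2 (127), and TOP1's NDR was at -0.50. No list was called. Compaction scores were lower at ribosomal proteins (-0.178, 37 of 120 higher) and glycolysis (-0.2, 2 of 16 higher, lost under another way of scoring), with ENO1 at -0.71. The a-specific list (0.296) lay high among random lists but held 2 genes, 1 higher and 1 lower. TOP1 had the highest score (0.85, on 153 reads) and ERR2 the lowest (-1.06). Their reach ratio differed from wild type by 0.054 (exact permutation p = 0.81).

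At 37 °C, with 1 NDR column per group, no test was made and intervals cover counting error only. The labels list 3 samples of wild type and 2 of each strain at 37 °C, and whether a column holds 1 or a pool is not given. Against 30 °C, wild type at 37 °C had more reads at ILV5 (log2 ratio 0.88, 95% interval 0.54 to 1.21), TAL1 (0.85, 0.52 to 1.17) and inside YEF3 (0.86, 0.62 to 1.10). It had fewer inside SWI1 (-0.79, -1.07 to -0.52) and MMS22 (-0.76, -1.01 to -0.52). Ribosomal proteins had a median of 0.219 (81 of 101 higher, percentile 99.94 among random lists), glycolysis 0.191 (14 of 20, 97.61) and Hsf1 targets 0.113 (11 of 16, 98.23). Its reach ratio was -2.76 ± 0.014 (SD, n = 2), a difference of -0.523 from 30 °C (exact permutation p = 0.0196, adjusted 0.0654), and -0.564 (permutation, adjusted 0.0245) without replicate 17, the lowest of wild type.

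The temperature-sensitive strains were set against wild type at 37 °C. In sth1-2, an allele of the RSC ATPase gene, the largest rises lay in subtelomeric repeat genes, whose reads cannot be placed in single copies: inside YRF1-5 (1.79, 1.59 to 2.0), YRF1-6 (1.51) and YRF1-1 (1.40). An NDR inside PMA1 stood at 1.22 (0.78 to 1.67), TPO4 at -1.41 (-2.17 to -0.72) and CIS3 at -1.41 (-2.30 to -0.61). Subtelomeric NDRs were high (0.147, percentile 100) and pericentromeric NDRs low (-0.113, 129 of 195 lower, percentile 0.0), with Hsf1 targets at -0.184 (1.9). Random lists ignore correlation between neighbouring NDRs, so NDR percentiles here are no test. The sth1-2 ribosomal protein genes were higher in compaction at 116 of 120 (median 0.975, against 0.199 to 0.441), led by RPL9B (2.18) and RPS20 (2.14), with TEF1 at 1.43. Glycolysis stood at 0.51 (14 of 16 higher) but was lost under another way of scoring. In rsc8-21, another RSC subunit allele, BSP1 stood at 0.97 (0.57 to 1.37), SYC1 at 0.88 (0.47 to 1.29), VAS1 at -1.18 (-1.73 to -0.66) and ILV5 at -1.0 (-1.71 to -0.35). Meiosis (-0.273, percentile 0.02) and stress-induced NDRs (-0.26, 0.01) were low and ribosome biogenesis high (0.072, 97.98). Compaction was higher at 102 of 120 ribosomal protein genes (median 0.516), with RPL32 at 1.39, and at NPL3 (0.97), and lists of alpha-specific genes (-0.387), seripauperins (-0.616) and pericentromeric genes (-0.002, lost under another way of scoring) lay low.

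In scc2-4, an allele of the cohesin loader gene, pericentromeric NDRs were low (-0.15, 131 of 195 lower, percentile 0.0), as were glycolysis (-0.208, 17 of 20 lower, 1.26), Hsf1 targets (-0.252, 0.13) and histone genes (-0.34, 0.44). PET111 stood at 1.10 (0.70 to 1.50), the NDR of YNR014W and PHO91 at -1.38 (-1.90 to -0.89), PMA1 at -1.09 (-1.93 to -0.31) and SCC2 itself at -0.23 (-0.71 to 0.24). No list lay outside the range of random lists in compaction. SAS4 (-0.87) was lowest and NFT1 (0.69) highest. In rgr1, an allele of a Mediator gene, COX13 stood at 0.76 (0.28 to 1.23), ERG6 at -0.92 (-1.47 to -0.40), the NDR of RPL13A and RPS16B at -0.83 and that of RPP1A at -0.81. Histone (-0.24, percentile 0.46), proteasome (-0.084, 0.83) and pericentromeric NDRs (-0.038, 0.92) were low, and ribosome biogenesis (0.081, 98.38), seripauperins (0.138, 99.99) and subtelomeric NDRs (0.062, 100) high. In compaction glycolysis genes were lower at all 16 (-0.304, lost under another way of scoring), pericentromeric genes were low (-0.202, 50 of 257 higher), and stress-induced (-0.245), Yap1 (-0.274, lost likewise) and alpha-specific genes (-0.586) were low, while ribosome biogenesis was high (-0.08). The B-type cyclin gene CLB2 stood at -0.70 and UBI4, a ubiquitin gene, at 0.47. Reach ratios, with 1 replicate each, differed from wild type at 37 °C by 0.079 in rgr1, 0.43 in rsc8-21, -0.13 in scc2-4 and 0.106 in sth1-2.

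The galactose, meiosis, alpha-specific and deleted-gene lists were not called by fry or camera in any NDR comparison at 30 to 32 °C, although 1 member of the meiosis list rose in diamide and RNH201 fell in rnh201d. In diamide the medians were -0.073 over 4 galactose NDRs, -0.006 over 18 meiosis NDRs and 0.078 over 12 NDRs of deleted genes, and in thiolutin they were 0.037, -0.002 and -0.013. The alpha-specific list has 1 NDR and was not tested. Median, mean and test also differed in sign, always without a call, for deleted genes in thiolutin, H4d4-14, med1d and rnh201d, galactose genes in med1d, rnh201d and rtt109d, meiosis genes in H4d4-14, H4R23A, ssu72-2 and the libraries labelled top1d, histones in med1d, ribosome biogenesis in rnh201d, seripauperins, stress-induced genes and Yap1 targets in H4R23A, a-specific, proteasome, stress-induced and Yap1 genes in the libraries labelled rpd3d, and ribosomal proteins in the libraries labelled top1d.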

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

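Of the tests in this part, that of library size for chromosome I and that of a shared batch for rtt109d were chosen after their results were seen, as were the fits with the batch block and those without wild-type replicate 17.

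The 3 ssu72-2 replicates shared a rise of NDR-spanning reads along chromosome I. Chromosome medians were centred within each replicate, which removes a scaling shared by all chromosomes, so they cannot test library size. They show that no other chromosome stood apart, with a largest absolute median of 0.11 in any replicate. A rise of contacts beyond copy number would put NDRs well above gene bodies, and the NDR median exceeded that of reads within genes by 0.19, under the bound of 0.3 set beforehand. Reads within genes of chromosome I, in another table, were 0.93 (log2) above the other chromosomes, so an extra copy of chromosome I may account for the pattern. Other groups lay between -0.07 and 0.05 in that measure, and no explanation beyond these was tested.

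With the batch block the changes of med1d correlated across NDRs with the change from 0.25X to 1X MNase at r = 0.511, and those of H4d4-14 at r = 0.52, so deeper digestion of the mutant libraries may account for part of them. Within batch the correlations were 0.265, 0.338 and 0.42 for med1d and 0.376 and 0.373 for H4d4-14, and single wild-type replicates ranged from -0.489 to 0.372. The lower reach ratio of both groups goes the way of more MNase, which moved it by -0.42 to -0.60 in the titration. An effect of the mutations on chromatin stays open, since digestion was not measured independently. NDRs are not independent replicates.

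Replicates 2 and 3 of rtt109d, and not replicate 1, had few reads near the ends of chromosomes I, VII, XIII and XIV, at 17 of the 18 NDRs where the W303 library had few. The other, on chromosome IV, stood at -0.41 and -0.4 (log2). Over the 18 the mean log2 deviations were -2.09 and -1.76, against -0.0 in replicate 1. A batch shared through the column-name number would lower wild-type libraries of the same numbers too, and these stood at -0.23 and -0.21, within the -0.33 to 0.74 of the other wild-type replicates. A strain background shared with W303 may account for the pattern, but at 16 other NDRs the correlation with W303 was 0.463 and 0.449, short of the 0.5 set beforehand, while wild-type replicates ranged from -0.667 to 0.625. With so few NDRs and this wild-type range, the background stays open. The rtt109d calls at chromosome ends rest on these replicates.

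Unexplained signals outside the comparisons follow. The direct comparison of diamide and thiolutin called 41 NDRs. For H4K16Q, whose scores enter no NDR test, 5 lists lay outside random lists. Reads in marker genes that BY4741 lacks stood above wild type: LEU2 by 6.33-fold in H4K16Q, 77.83-fold in rnh201d, 50.67-fold in rtt109d, 79.61-fold in ssu72-2 and 47.98-fold in libraries labelled top1d. MET17 stood 9.57-fold higher in H4K16Q, 120.01-fold in med1d, 73.16-fold in rtt109d, 107.39-fold in ssu72-2 and 59.68-fold in the libraries labelled top1d. URA3 stood 27.66-fold higher in H4K16Q, 29.51-fold in H4R23A, 27.37-fold in H4d4-14, 22.08-fold in rtt109d and 19.81-fold in ssu72-2. Reads in mitochondrial genes were 0.25% of wild type in ssu72-2 (367 reads) and 19.2% in thiolutin. RPD3 (89.4%) and TOP1 (49.3%) were given above.

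Other splits of the same replicates (100 drawn of 969 possible) tested whether chance can give as many calls. It was excluded for rtt109d, where the real split in a fit of 2 groups called 44 NDRs, 1 split reached this, and the highest other called 5. For med1d (7 called) and ssu72-2 (274) the share, 3 of 100 splits with the real one included, lies under the 5% that excludes it, but other splits reached 573 and 690. Both of these put wild-type replicates 16 and 17 in one group, with med1d replicate 3 or ssu72-2 replicate 1, which points to a structure among the wild-type libraries. Without med1d replicate 3 no NDR passed in edgeR (376 at an unadjusted p under 0.05). With the batch block 464 NDRs passed in med1d and 313 in ssu72-2, and without wild-type replicate 17 the counts were 16 and 405.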

How the results depend on the processing

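The batch block, the fits without wild-type replicate 17, the counts without chromosome I, without NDRs next to strain genes or within the range of the W303 library, and the within-batch reach ratios were chosen after the data were seen, and the rest were planned. Of the values that answer a comparison, 185 were the same under an alternative, 86 moved, 5 passed a threshold they had not passed, and 9 reversed. Of lists, 77 values of the NDR tests were the same, 30 lost their call and 1 reversed, and 205 of compaction were the same and 77 lost theirs. Of named NDRs 1722 values were the same, 404 lost their call, 4 gained one and 3 reversed, and of named compaction genes 1633 were the same and 780 moved. Causes were not tested. At these depths simulated med1d counts recovered 26.9% of NDRs changed 1.5-fold and 80.6% at 2-fold. NDR comparisons at 37 °C have 1 column per group and no counts of calls, so no alternative gives one.

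Counts of NDRs past the threshold were 2 in H4R23A, 2 in H4d4-14, 320 in diamide, 7 in med1d, 3 in rnh201d, 54 in rtt109d, 288 in ssu72-2, 241 in thiolutin and 0 in the libraries labelled rpd3d and top1d. With all pairs as library size they were 0 in H4R23A, 5451 in H4d4-14, 0 in diamide, 0 in med1d, 0 in rtt109d, 3 in ssu72-2 and 0 in thiolutin, by edgeR, and in H4d4-14 the NDR of RRN11 turned to -0.39 (adjusted p = 0.523), that at chromosome XIII position 194810 to -0.46 (0.4745) and that of RPD3 to -1.65 (0.02378). With the batch block they were 0 in H4R23A (351 at an unadjusted p under 0.05), 498 in H4d4-14, 139 in diamide, 464 in med1d, 9 in rnh201d, 123 in rtt109d, 48 in thiolutin and 4 in the libraries labelled top1d, and without wild-type replicate 17 as well 531 in H4d4-14, 206 in diamide, 506 in med1d, 8 in rnh201d, 146 in rtt109d, 23 in thiolutin and 4 in the libraries labelled top1d. The glycolysis list in H4R23A turned its test direction with the batch block (median 0.115, camera adjusted p = 0.999).

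DESeq2 called 1 in H4R23A, 14 in med1d and 5 in rnh201d. Every library as a replicate gave 14 in H4R23A, 11 in H4d4-14, 16 in med1d and 576 in ssu72-2. Against H4-WT the counts were 0 in H4R23A and 0 in H4d4-14, and against wild type at 32 °C 80 in ssu72-2. Without NDRs next to strain genes they were 1 in H4R23A, 4 in med1d and 0 in rnh201d, and without chromosome I 163 in ssu72-2. Leaving out 1 replicate gave 1 to 4 in H4R23A, 0 to 3 in H4d4-14, 58 to 386 in diamide, 0 to 16 in med1d, 0 to 3 in rnh201d, 11 to 69 in rtt109d, 117 to 405 in ssu72-2 and 72 to 437 in thiolutin. A lone replicate was taken to vary like the other groups.

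The replicate block, with samples paired by replicate number, gave 109 in H4R23A, 560 in H4d4-14, 484 in diamide, 0 in med1d (485 at an unadjusted p under 0.05), 10 in rnh201d, 490 in the libraries labelled rpd3d, 171 in ssu72-2 and 55 in thiolutin. Residuals of same-numbered replicates correlated at a median of 0.029 (113 pairs), so the numbers do not pair the samples. The counts of rtt109d and the libraries labelled top1d were 45 and 0.

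The reach difference of H4d4-14 was -0.655 with every library (adjusted p = 0.0068) and -0.855 to -0.441 with 1 replicate left out, that of med1d was -0.461 (0.0376) and -0.537 to -0.352, and that of wild type at 37 °C was -0.564 to -0.513. Over all 4 orientations the difference was -0.804 in rgr1, 0.187 in the libraries labelled rpd3d, 1.264 in rsc8-21, 1.244 in scc2-4, 1.24 in sth1-2 and -0.911 in the libraries labelled top1d, and with 300 to 1000 over 100 to 300 bp it was 0.096 in rgr1, 0.326 in rsc8-21 and 0.074 in sth1-2. Thiolutin stood at 0.101 within batch and at -0.475 to 0.036 with 1 replicate left out, and the libraries labelled top1d at -0.179 to 0.287. Relative to wild type, the library without crosslinking stood at 1.67, with all 4 orientations at -5.95 and with the other window at 0.85, and the library without ligation at 0.74, -13.16 and 0.33. The MNase difference of -0.5 was -1.35 over all 4 orientations.

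Of compaction lists, H4R23A had 7 outside by log2 long over short, also 7 at a pseudocount of 0.1, the libraries labelled rpd3d had 2 and scc2-4 1 by log2 long over short at every pseudocount, and med1d 5 at a pseudocount of 1. With a minimum of 20 reads there were 1 in H4d4-14, 5 in thiolutin, 2 in scc2-4 and 4 in sth1-2. Of 31 camera calls, 8 held with an estimated correlation. Shared boundaries were 35.4% within 100 bp and 74.1% within 500 bp, 54.2% for those with lower and 46.5% for those with higher strength values.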

Other observations

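The tests of shared controls, digestion and promoter against gene body in this part were set before their results were seen, except those of shared controls as the whole cause and of the MNase change at NDRs called in both treatments, which were chosen after.

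H4K16Q, in which the H4 lysine that Sir proteins read carries a change, has 1 pooled column of compaction scores and was set against wild type at 30 °C without a test. Subtelomeric genes were lower (median -0.122, 54 of 147 higher, against -0.016 to 0.074 for random lists), with YHR218W at -1.23 and IMD2, an enzyme of GTP synthesis, at -0.88. Glycolysis was lower (-0.225, 3 of 16 higher, against -0.119 to 0.173), with TDH2 at -0.64 and ENO1 at -0.59. Ribosomal proteins (0.002, 61 of 120 higher, against 0.06 to 0.23), with RPL15A at -0.92 and RPL4B at -0.91, and ribosome biogenesis (-0.065, 18 of 52 higher) were low, and meiosis genes were high (0.201, 22 of 29). SST2, a regulator of pheromone signalling, stood at 0.87 and the mitochondrial gene Q0045 at 1.86. The calls of meiosis, ribosomal proteins and ribosome biogenesis were lost under at least 1 other way of scoring.

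W303, another laboratory strain, had 1 library, which lay over 1 (log2) outside the wild-type range at 18 NDRs. These lay at the ends of chromosomes I, VII, XIII and XIV and near HXT genes on chromosome IV. HXT17, a hexose transporter gene, had 6.6 CPM against 90.8 ± 19.1 (SD, n = 16) in wild type, and an NDR inside COS12 had 10.2 against 113.4 ± 25.0 CPM. In the other single libraries 2 NDRs lay outside in wild type at 32 °C, 2 in H4Q93E, 0 in H4-WT and 0 in H4K16Q, where 1 library gives no test.

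Reads in mitochondrial genes varied widely between pooled columns. As a percentage of wild type they stood at 26.0 in diamide, 27.9 in med1d, 66.5 in rtt109d, 69.9 in the libraries labelled top1d, 73.0 in H4d4-14, 116 in the libraries labelled rpd3d, 172 in rnh201d, 258 in H4R23A and 308 in H4K16Q, and against wild type at 37 °C at 23.2 in sth1-2, 30.2 in rsc8-21, 88.9 in rgr1 and 316 in scc2-4.

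Genes whose promoter NDR lost spanning reads may also lose compaction. Across 2132 genes the changes correlated at r = 0.419 in diamide (0.348 without ribosomal protein genes) and across 2130 genes at r = 0.383 in thiolutin (0.34), above the 0.2 set beforehand. In other groups r was 0.204 in ssu72-2, 0.151 in med1d, 0.096 in rtt109d, 0.085 in rnh201d, 0.084 in H4d4-14, 0.03 in H4R23A, and 0.028 and 0.031 in the libraries labelled rpd3d and top1d. Genes are not independent replicates, and both measures come from the same libraries.

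Diamide and thiolutin were set against the same wild-type libraries, which by itself makes their changes correlate. With the wild-type replicates split, so that none served both, the correlation stayed above 0 in all 100 splits, with 0.052 the lowest and 0.266 the mean, so shared controls are not the whole cause. How much they add was left open, since that mean lies between the bounds of 0.1 and 0.3 set beforehand. Deeper MNase digestion of the treated libraries was left open by the test, since the correlations with the MNase change of 0.035 for diamide and 0.303 for thiolutin met neither bound (both over 0.5, or both under 0.2). With the batch block they were 0.07 and 0.087, and within batch 0.055 and 0.059 for diamide and 0.143 and -0.024 for thiolutin, all under 0.2. These run over all NDRs, and the 77 NDRs called up in both lay at a median percentile of 72.3 of the MNase change (quartiles 53.0 and 84.6), the way digestion needs, while the 6 called down in both, at 59.4, did not lie low. It was therefore not excluded for the shared rises.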
